A study of Homo sapiens with 30 samples.

How the data were processed

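Proliferating human peripheral blood mononuclear cells of 3 donors were profiled by the submitters on Affymetrix HuGeneFL arrays with 7129 probe sets, infected with HIV-1 RF or left uninfected, at 0, 12, 24, 48 and 72 h, 30 arrays in all. How the cells were stimulated, how much virus was used, how long after adding it the 0 h samples were taken and how the chips were read are not given in the sources used here. The deposited values are linear intensities, not log transformed, of which 30.3% are negative (23.4 to 37.7% per array), as differences between perfect match and mismatch probes can be. They appear to have been scaled by the authors, since the 2% trimmed mean of the deposited intensity was about 2005 on 22 arrays and about 2507 on 8. No column was left unassigned, and no 2 arrays held identical values.

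Each array was scaled to a common 2% trimmed mean of 2139. The floor was the median over arrays of the 95th percentile of the size of the negative values, 3961. Values under the floor were set to it and log2 was taken. A probe set was tested if it lay above the floor on at least 3 of the 30 arrays, which left 2003 probe sets and 1555 genes. Per array, 1082 to 1494 probe sets were above the floor, and 182 of those tested were above it on every array. The 58 control probe sets and 17 probe sets of sex-linked genes were left out. Of the probe sets, 5709 carried 1 gene symbol, 321 several and 1099 none, and only those with 1 symbol were named. The number of arrays limits the precision.

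Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of all 30 arrays with the 10 groups and the donor as a fixed block, followed by empirical Bayes moderation (18 residual and 2.07 prior degrees of freedom). Two-sided p values were adjusted by Benjamini and Hochberg over the 2003 probe sets of a comparison, with a threshold of 0.05. The comparisons were infected minus uninfected averaged over 12 to 72 h, the same at each of the 5 times, an F test of whether that difference varied with time, an F test of time in uninfected cells, and uninfected cells at 72 h minus 0 h. Donor numbers in the labels pair the arrays, and the labels call each control autologous. The residuals of an infected and an uninfected array of the same donor and time, taken as deviations from group means, had a median correlation of 0.39 over 15 pairs, against -0.188 over 300 pairs of arrays from different donors. The donors' deviations cancel within each group, so the negative value follows from the positive one. Arrays of the same donor at any times had 0.369 over 135 pairs. These correlations are across probe sets, which are not independent replicates.

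Gene lists were tested with camera (preset correlation 0.01), using for each gene the probe set with the highest mean, in lists with at least 5 measured members. This was so for 26 of 30 lists. Adjusted p values are over the lists of 1 comparison, and the same test with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. A list score is the mean of its members' log2 differences in 1 donor at 1 time, minus the mean over all genes tested. Members were also adjusted over the list alone. Counts of members that rose or fell use the test over all genes.

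Genes were named by a fixed rule. For each comparison of 2 groups these were the 10 largest rises and 10 largest falls among genes that passed and moved the same way in 3 of 3 donors. With fewer than 5 such genes, the 10 with the lowest p and the same direction in 3 of 3 donors were named and said not to pass. For F tests the 10 lowest p were named, and for gene lists up to 4 members with the lowest p. A fixed set of genes of T-cell activation, interferon response and HIV-1 entry was also named whether or not they passed, and not all of its members are reported here. Folds against a group with 0 arrays above the floor are lower bounds. The comparisons, lists, naming rule, floor and filter were chosen before the data were examined.

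Alternatives chosen at that point were floors at 0.5 and 2 times the main one, quantile normalization, values as deposited, no filter, a filter of 15 of the 30 arrays, no donor block, a donor block within each time, limma with trend and robust moderation, only the 6 arrays of a comparison, each donor's own mean difference, each time left out of the average, each replicate left out in turn, and for lists the mean over a gene's probe sets. Added after the data were seen were the omission of 3 arrays whose ACTB or GAPDH control ratio lay beyond 3-fold, together and singly, array weights, a floor at 0.1 times the main one, and the list tests on values as deposited. The procedure was tested on simulated data with 2003 probe sets of the same design. It recovered 77.6% of changes of 1 log2 unit in the comparison averaged over time and 41.8% at a single time, with 5 false calls of 148 and 9 of 87. Of simulated lists without a change, 1.5% fell under 0.05. The noise was drawn independently for each probe set, so members of simulated lists were not correlated, and no array was made to stand apart. The 1.5% therefore does not give the error rate of camera on lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.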

Results

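Human peripheral blood mononuclear cells, the lymphocytes and monocytes of blood, were compared with and without infection by the laboratory strain HIV-1 RF at 0, 12, 24, 48 and 72 h. Each of the 10 groups held 1 array from each of 3 donors, and each infected culture had an uninfected control from the same donor. Log2 differences and folds below come from intensities in which values under the floor of 3961 were set to the floor, so a fold is understated where arrays lie under it. Group means are given as intensity before the floor, with the SD between arrays.

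Averaged over 12 to 72 h, interferon-stimulated genes were higher as a group in infected than in uninfected cells, with 19 of 27 measured members higher and a median log2 difference of 0.08 (camera adjusted p = 0.00345). The list had an adjusted p = 0.596 with an estimated correlation and a fry adjusted p of 0.502. The list score was not raised in every donor. In replicate 1 it was -0.278 at 12 h, 0.004 at 24 h, -0.014 at 48 h and 0.058 at 72 h. In replicate 2 it was above 0 at each of these times, and in replicate 3 from 24 h on. ISG15, a ubiquitin-like protein made in response to interferon, had the lowest p of the list, at 7559 ± 3870 (SD, n = 12 arrays) in infected and 3450 ± 2821 in uninfected cells. Its log2 difference was 0.61 ± 0.16 (SE), or 1.53-fold higher, with 3 of 3 donors higher and a limma adjusted p of 0.421, which did not pass. SP110, a nuclear body protein, was higher in 3 of 3 donors with a log2 difference of 0.25 ± 0.09. PSMB9, an immunoproteasome subunit on the same list, was lower in 3 of 3 donors at -0.31 ± 0.11. Over all genes tested 0 members rose, and adjusted over the list alone 1 did (ISG15, adjusted p = 0.029).

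Among single genes in the same comparison, the lowest p belonged to SLA (probe set D89077_at), an adaptor that dampens T-cell receptor signalling, at 6530 ± 1421 (SD, n = 12 arrays) in infected and 4499 ± 2198 in uninfected cells. The log2 difference of SLA was 0.41 ± 0.10 (SE), higher in 3 of 3 donors, with an adjusted p of 0.421. The other named genes were lower in infected cells in 3 of 3 donors, with log2 differences from -0.50 to -0.30 and adjusted p from 0.421 to 0.599. They included PPP1CC, a catalytic subunit of protein phosphatase 1, SMS, which makes spermine, and SLC25A5, the mitochondrial carrier of ADP and ATP. The rest were the proteasome subunit PSMB5, the mitochondrial ribosomal protein MRPL3, the kinase MAPKAPK2, the cell-cycle protein CKS2, and LAGE3. The chemokine CCL5 had a log2 difference of 0.58 ± 0.28 (higher in 3 of 3 donors, adjusted p = 0.613). CXCR4, a coreceptor for HIV-1, had -0.16 ± 0.18 (lower in 2 of 3 donors, adjusted p = 0.785). MX1, an antiviral GTPase, had 0.29 ± 0.15 (higher in 2 of 3 donors), and IL2RA, the interleukin 2 receptor alpha chain, had -0.25 ± 0.17. CCL4 had -0.03 ± 0.23, the death receptor FAS -0.11 ± 0.07, the cell-cycle inhibitor CDKN1A -0.07 ± 0.09, IL2 -0.06 ± 0.15 and cyclin B1 (CCNB1) -0.03 ± 0.04. CD4, IFNG, TNF, CXCL10, IFIT1 and MKI67 were above the floor on 0 or 1 of the 30 arrays and were not tested. CCL3 had no probe set with that symbol alone. By limma, 0 of 2003 probe sets passed, with 158 at an unadjusted p under 0.05, of which 52 were higher and 106 lower in infected cells. The count was 3 on values as deposited, 11 without replicate 1 and 48 with array weights. The interferon list's adjusted p was 0.471 without replicate 2 and 0.124 without replicate 3. Without replicate 1, genes of MHC class II antigen presentation (camera adjusted p = 0.0205), glycolysis (0.0288), ribosomal proteins (0.0288) and oxidative phosphorylation (0.0401) were lower. T-cell receptor and surface genes and genes of endoplasmic reticulum stress and amino acid response (0.0459 each) were higher. These lists had 0.195 to 0.812 with an estimated correlation and 0.0347 to 0.602 by fry.

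At 72 h the interferon-stimulated genes were higher in infected cells with the lowest camera p of any list in the infection comparisons, with 21 of 27 members higher, 3 lower and 3 with no difference above the floor, and a median log2 difference of 0.33 (camera adjusted p = 6.12e-11). With an estimated correlation the list had an adjusted p = 0.176, and its fry adjusted p was 0.508. ISG15 (probe set M13755_at) was 8997 ± 3312 (SD, n = 3) in infected and 3591 ± 1152 in uninfected cells. Its log2 difference was 1.02 ± 0.32 (SE), 2.03-fold, higher in 3 of 3 donors with an adjusted p of 1. IFI44 differed by 0.67 ± 0.24 and IFI44L by 0.49 ± 0.17, each higher in 2 donors and lower in 0, and SP110 by 0.49 ± 0.19 in 3 of 3 donors. MX1 was at least 1.74-fold higher, since 0 of 3 uninfected arrays were above the floor, with 2 donors higher and 0 lower. Over all genes tested 0 members rose, adjusted over the list alone 0 rose, and 7 were higher at an unadjusted p under 0.05. The donors' mean list score was 0.31 ± 0.24 (SD, n = 3) at 72 h, with 3 of 3 donors higher, against -0.07 ± 0.23 at 12 h. It was 0.15 ± 0.14 at 0 h and 0.04 ± 0.04 at 24 h, also with 3 of 3 donors higher at each.

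**Figure D1:**
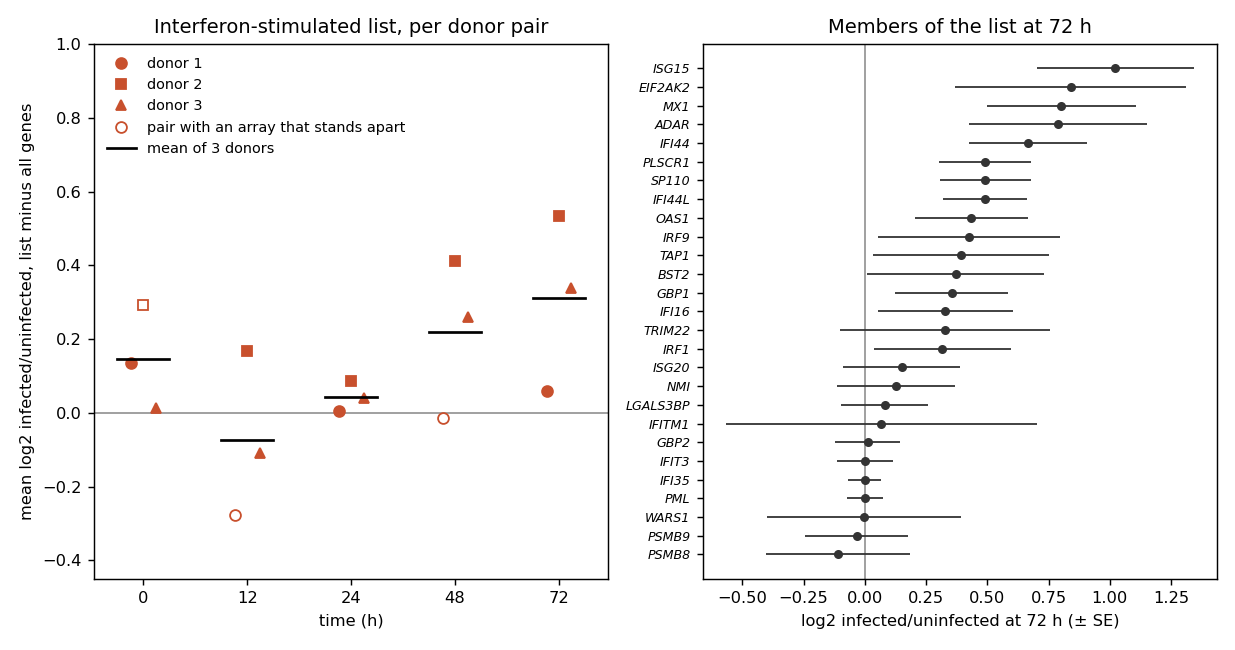
Left, the score of the interferon-stimulated list per donor against time in hours. The score is the list's mean log2 difference (infected minus uninfected) minus that of all genes. Open points are pairs that hold an array standing apart in the control ratios, and a bar is the mean. Right, the log2 difference ± SE of the 27 members at 72 h. At 0, 24 and 72 h 3 of 3 donors lie above 0, and at 72 h 21 of 27 members are higher in infected cells.

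Genes of glycolysis were lower as a group in infected cells at 72 h, with 14 of 16 members lower (camera adjusted p = 0.00151; adjusted p = 0.275 with an estimated correlation). ALDOC, an aldolase, differed by -0.76 ± 0.34 (log2 ± SE, lower in 2 of 3 donors) and PGK1, phosphoglycerate kinase, by -0.53 ± 0.34 (lower in 3 of 3 donors). Genes of oxidative phosphorylation were lower in 18 of 28 members (camera adjusted p = 0.039; adjusted p = 0.383 with an estimated correlation). COX5B had -0.62 ± 0.26 and was lower in 3 of 3 donors. Ribosomal protein genes were lower in 34 of 41 members with a median of -0.12 (camera adjusted p = 0.0465; adjusted p = 0.431 with an estimated correlation). RPL24 had -0.57 ± 0.32. By fry the 3 lists each had an adjusted p of 0.824. In each of them 0 members fell over all genes tested and 0 fell adjusted over the list alone. Other named genes at 72 h had an adjusted p of 1. Higher in 3 of 3 donors were ARHGAP1, a GTPase-activating protein (0.57 ± 0.16), LMNB2, a nuclear lamin (0.36), FLOT2 (0.52), NFKBIA, the inhibitor of NF-kB (0.67), CDA, cytidine deaminase (0.74), and MVP, the major vault protein (0.77). MAPKAPK2 was lower by at least 1.56-fold, with 0 of 3 infected arrays above the floor. By limma 0 of 2003 probe sets passed and 29 had an unadjusted p under 0.05, 19 higher and 10 lower. The glycolysis list had an adjusted p of 0.581 without replicate 2, the oxidative phosphorylation list 0.481, and the ribosomal list 0.581. Without replicate 3 the oxidative phosphorylation list had 0.197 and the ribosomal list 0.289. Without the 3 arrays that stood apart in the control ratios the oxidative phosphorylation list had 0.0596. Under quantile scaling the ribosomal list had 0.36 and the oxidative phosphorylation list 0.0535, and as deposited they had 0.0947 and 0.186.

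At 48 h interferon-stimulated genes were again higher as a group in infected cells, with 15 of 27 members higher and 10 lower (camera adjusted p = 0.0465; adjusted p = 0.768 with an estimated correlation; fry adjusted p = 0.685). The list score was 0.22 ± 0.22 (SD, n = 3 donors), higher in 2 of 3 donors. ISG15 was 10010 ± 4483 (SD, n = 3) in infected and 3423 ± 2918 in uninfected cells, a log2 difference of 1.01 ± 0.32 (SE), higher in 3 of 3 donors. IFITM1, an interferon-induced membrane protein, differed by 1.69 ± 0.63 in 3 of 3 donors. Neither passed (adjusted p = 0.427 for each), and adjusted over the list alone 0 members rose. Ribosomal protein genes differed both ways, 22 of 41 higher and 19 lower, with a median of 0.96 and a mean of 0.53 (camera adjusted p = 0.0465; adjusted p = 0.652 with an estimated correlation; fry adjusted p = 0.685). RPS15 had 1.36 ± 0.55 and RPL24 -0.85 ± 0.32, and 0 members rose or fell over all genes tested or adjusted over the list alone. The mean ribosomal score per donor was 0.53 ± 1.10 (SD, n = 3), higher in 1 of 3 donors. The uninfected array of replicate 1 at this time had a GAPDH 3'/5' ratio of 0.293 and a median correlation of 0.557 with the other arrays of its donor. Without the 3 arrays that stood apart in the control ratios, the ribosomal list had an adjusted p of 0.258 and the interferon list 0.00023.

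Single genes with the lowest p at 48 h included RBBP4, a histone-binding subunit of chromatin complexes, at 4524 ± 185 (SD, n = 3) in infected and 9597 ± 2153 in uninfected cells. The log2 difference of RBBP4 was -1.06 ± 0.25 (SE) and that of CSK, the kinase that inhibits Src family kinases, -1.04 ± 0.32, each lower in 3 of 3 donors with an adjusted p of 0.427. PPP1CC (-0.73), PSMB5 (-0.56) and the mitochondrial ribosomal protein MRPL23 (-0.91) were lower in 3 of 3 donors. DNAJC7 was lower by at least 1.33-fold, with 0 of 3 infected arrays above the floor. The mitotic kinase PLK1 (0.76 ± 0.19), ARHGAP1 (0.60), SLA (0.68) and topoisomerase TOP2A (0.81 ± 0.24) were higher in 3 of 3 donors. Another TOP2A probe set differed in direction. CCL5 had a log2 difference of 1.38 ± 0.56, higher in 3 of 3 donors, and CXCR4 had -0.79 ± 0.37, lower in 3 of 3 donors (adjusted p = 0.427 for each). By limma 0 of 2003 probe sets passed and 216 had an unadjusted p under 0.05, 94 higher and 122 lower. Without the uninfected array of replicate 1 at 48 h, 1 passed and 35 had an unadjusted p under 0.05. The interferon list had an adjusted p of 0.0527 under quantile scaling, 0.0728 as deposited, 0.575 without replicate 2 and 0.273 without replicate 3.

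At 24 h fewer probe sets had an unadjusted p under 0.05 in the main fit than at any other time, and 0 of 26 gene lists passed (lowest camera adjusted p = 0.0987). The ranking did not hold with only the 6 arrays of a comparison, where 98 had one at 24 h and 22 at 48 h. TGFBR2, a receptor for transforming growth factor beta, was 6321 ± 1046 (SD, n = 3) in infected and 4452 ± 424 in uninfected cells, a log2 difference of 0.50 ± 0.22 (SE). UBXN4 (0.62), the cold-inducible RNA-binding protein RBM3 (0.63), FKBP2 (0.41), POFUT1 (0.47) and SEMA4D, a semaphorin on T cells (0.66), were likewise higher in 3 of 3 donors. CKS2 (-0.69), the translation factor EIF2S1 (-0.41), MTHFD1 of folate metabolism (-0.52) and FAH (-0.31) were lower in 3 of 3 donors. Each of these genes had an adjusted p of 1. Without replicate 1, 4 lists passed: proteasome (adjusted p = 2.17e-04), oxidative phosphorylation (0.00257) and ribosomal protein genes (0.0197) were lower, and T-cell receptor and surface genes (0.0495) higher. With an estimated correlation these had 0.414, 0.414, 0.792 and 0.414, and by fry 0.333, 0.333, 0.7 and 0.7. Ribosomal protein genes were also lower without the 3 arrays that stood apart (0.0049), and genes of endoplasmic reticulum stress and amino acid response were higher on values as deposited (0.0411). These 2 had 0.703 and 0.646 with an estimated correlation and 0.778 and 0.994 by fry. By limma 0 of 2003 probe sets passed and 11 had an unadjusted p under 0.05, 3 higher and 8 lower. Without replicate 1 the count passing was 2.

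At 12 h heat shock genes were higher as a group in infected cells by camera (adjusted p = 0.026; adjusted p = 0.949 with an estimated correlation), although 6 of 13 members were higher and 6 lower, with a median of 0 and a mean of 0.21. HSPB1, a small heat shock protein, differed by 1.08 ± 0.29 (log2 ± SE), higher in 2 donors and lower in 0. DNAJB1 differed by 1.10 ± 0.38, HSPA6 by 0.93 ± 0.35 and HSPH1 by 0.62 ± 0.25. Over all genes tested 0 members rose, and adjusted over the list alone 1 did (HSPB1, adjusted p = 0.0154). Ribosomal protein genes were higher in 23 of 41 members with a median of 0.08 and a mean of 0.37 (camera adjusted p = 0.00582; adjusted p = 0.949 with an estimated correlation), with 0 members rising over all genes tested or adjusted over the list alone. RPL34 had 1.85 ± 0.85 and was higher in 3 of 3 donors. The uninfected array of replicate 1 at 12 h had an ACTB 3'/5' ratio of 22.3. Without the 3 arrays that stood apart the ribosomal list had an adjusted p of 0.642 and the heat shock list 0.0216. By fry each of the 2 lists had an adjusted p of 0.895. The signalling subunit GNAS was 38190 ± 3115 (SD, n = 3) in infected and 16720 ± 14910 in uninfected cells, 2.82-fold higher in 3 of 3 donors. Lower in 3 of 3 donors were IARS1, an aminoacyl-tRNA synthetase (-0.49), PSMB5 (-0.52), CSNK2B (-0.76), PEA15 (-0.40), HAX1 (-0.77), FKBP2 (-0.56), PPP1CC (-0.60), TRA2A (-0.43) and ATXN2L (-0.74), and each of these genes had an adjusted p of 1. By limma 0 of 2003 probe sets passed and 73 had an unadjusted p under 0.05, 29 higher and 44 lower, and leaving out replicate 1 the count passing was 4. The heat shock list had an adjusted p of 0.443 without replicate 2, 0.413 without replicate 3 and 0.0543 with the mean over a gene's probe sets. The ribosomal list had 0.171 without replicate 1 and 0.119 without replicate 2.

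At 0 h KLF6 and RGS16 were lower in infected than in uninfected cells, and DUSP5, SGK1 and SRF were lower without passing. KLF6 (probe set U44975_at), a zinc finger transcription factor, was 7415 ± 1669 (SD, n = 3) in infected and 13700 ± 1978 in uninfected cells. Its log2 difference was -0.90 ± 0.17 (SE), 1.87-fold lower in 3 of 3 donors (adjusted p = 0.0267). RGS16 (probe set U70426_at), a regulator of G protein signalling, was 2026 ± 580 and 8169 ± 4110, at least 1.91-fold lower in 3 of 3 donors (adjusted p = 0.0267), with 0 of 3 infected arrays above the floor. The third probe set that passed carries the symbols of 2 histone H2A genes and was higher, with a log2 difference of 0.70 ± 0.11 (adjusted p = 0.00652). Lower in 3 of 3 donors with an adjusted p of 0.064 were the phosphatase DUSP5 (-0.96 ± 0.22), the kinase SGK1 (-0.71), ZNF267 (-0.87), the apoptosis initiator CASP8 (-0.85), the transcription factor SRF (-0.85), ABAT (-0.95) and CYP1A2 (-1.61 ± 0.42). ADA, adenosine deaminase, was higher in 3 of 3 donors at 0.78 ± 0.22 (adjusted p = 0.0792). CXCR4 was lower in 3 of 3 donors at -1.16 ± 0.37 (adjusted p = 0.105). The uninfected array of replicate 2 at 0 h had an ACTB 3'/5' ratio of 15.9 and a GAPDH ratio of 2.69. By limma 3 of 2003 probe sets passed, 1 higher and 2 lower, and 297 had an unadjusted p under 0.05, 61 higher and 236 lower. Without replicate 2 the count was 0, and without replicate 1 it was 233. Without replicate 3 KLF6 and RGS16 did not pass (adjusted p = 0.596 and 0.342). Neither gene passed under quantile scaling (adjusted p = 0.087 for each) or on values as deposited (0.0787 for each). The same held with the donor block within each time, and 0 probe sets passed with only the 6 arrays of the comparison. Without the uninfected array of replicate 2 KLF6 had a log2 difference of -0.89 (adjusted p = 0.0996). Without the 3 arrays that stood apart both genes passed, KLF6 at -0.92 (adjusted p = 0.00556) and RGS16 at -1.08 (adjusted p = 0.0159).

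Apoptosis genes were lower as a group at 0 h, with 14 of 16 members lower (camera adjusted p = 0.0367; adjusted p = 0.216 with an estimated correlation; fry adjusted p = 0.00831). Adjusted over the list alone 4 members fell, against 0 over all genes tested. They were CASP8, the inflammatory caspase CASP5 (-1.22 ± 0.35), the caspase 8 inhibitor CFLAR (-0.50 ± 0.17) and the inhibitor of apoptosis BIRC2 (-0.35 ± 0.12). Genes of oxidative phosphorylation were higher in 22 of 28 members (camera adjusted p = 0.00546; adjusted p = 0.216 with an estimated correlation). UQCRC1 had 0.71 ± 0.28 and was higher in 3 of 3 donors. Glycolysis genes were higher in 12 of 16 members (camera adjusted p = 0.0367; adjusted p = 0.42 with an estimated correlation), with the pyruvate kinase PKM at 1.01 ± 0.38 in 3 of 3 donors. T-cell receptor and surface genes were higher in 11 of 15 members (camera adjusted p = 0.0367; adjusted p = 0.417 with an estimated correlation), with CD7 at 1.28 ± 0.41 and the receptor chain CD3E at 0.77 ± 0.37, each in 3 of 3 donors. In these last 3 lists 0 members rose, over all genes tested or adjusted over the list alone. By fry the oxidative phosphorylation list had an adjusted p of 0.285, the glycolysis list 0.467 and the T-cell list 0.377. Among markers of other cell types at 0 h, the monocyte markers LYZ (-1.27 ± 0.44, lower in 3 of 3 donors, adjusted p = 0.149) and APOE (-0.50 ± 0.13, lower in 2 donors and higher in 0, adjusted p = 0.064) were lower without passing over all genes tested. Adjusted over the list alone these 2 fell, and the monocyte list had a camera adjusted p of 0.873. APOE had a mean intensity over all arrays of 1458, under the floor. Without the 3 arrays that stood apart its difference was -0.30 (limma adjusted p = 0.211). The B-cell markers differed in direction: CR2 had -1.18 ± 0.34 (lower in 2 donors and higher in 0, adjusted p = 0.0787), CD79A -0.33 ± 0.13 (adjusted p = 0.221) and CD37 0.84 ± 0.44 (adjusted p = 0.392). The platelet marker SELP had -1.22 ± 0.45 (lower in 2 of 3 donors, adjusted p = 0.176) and granulysin (GNLY) of cytotoxic cells 1.34 ± 0.56 (higher in 3 of 3 donors, adjusted p = 0.239). The cytotoxic list had a camera adjusted p of 0.211. Without the 3 arrays that stood apart the glycolysis list had an adjusted p of 0.649 and the T-cell list 0.237. Under quantile scaling the apoptosis list had 0.132, the glycolysis list 0.0813 and the T-cell list 0.0813. On values as deposited the apoptosis list had 0.0966. Without replicate 1 the apoptosis list had 0.0758 and the T-cell list 0.239, without replicate 2 the glycolysis list had 0.48 and the T-cell list 0.322, and without replicate 3 the apoptosis list had 0.187 and the glycolysis list 0.0579.

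The difference between infected and uninfected cells did not itself differ detectably between the 5 time points. The lowest p among named genes belonged to RGS16, SRF and KLF6, which were lower in infected cells at 0 h (log2 differences -0.93, -0.85 and -0.90) and at 24 h had differences of 0.00, 0.35 and 0.22. RGS16 and KLF6 lay at the floor in uninfected cells at 24 h, so their differences there could not be negative. ARHGAP1 had 0.03 at 0 h and 0.57 at 72 h, PLK1 -0.31 at 24 h and 0.76 at 48 h, and RBBP4 0.37 at 24 h and -1.06 at 48 h. FKBP2 had -0.56 at 12 h and 0.41 at 24 h, and the kinase CSNK1D -0.62 at 0 h. The transporter SLC6A11 had -0.61 at 0 h, and FOS, a component of the transcription factor AP-1, had 0.81 at 0 h. At later times FOS had 0, since both groups lay at the floor. Each of these 10 genes had an adjusted p of 0.998. By the limma F test 0 of 2003 probe sets passed and 51 had an unadjusted p under 0.05, and the count passing was 24 without replicate 1.

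In uninfected cells, CCL4, CXCR4, KLF6 and DUSP5 fell from 0 h to 72 h, and TFRC, immunoproteasome subunits and, as a group, genes of DNA replication rose. CCL4 (probe set J04130_s_at), a chemokine, fell from 38870 ± 16620 (SD, n = 3) to 8994 ± 2624, a log2 change of -2.07 ± 0.47 (SE), 4.19-fold (adjusted p = 0.0219). CXCR4 (probe set L06797_s_at) fell from 37220 ± 25860 to 9483 ± 4002, a change of -1.82 ± 0.37, 3.52-fold (adjusted p = 0.00896). KLF6 fell from 13700 ± 1978 to 3293 ± 1553, a change of -1.71 ± 0.17 (adjusted p = 7.3e-06). DUSP5 changed by -1.61 ± 0.22 (adjusted p = 2.63e-04). TFRC (probe set X01060_at), the transferrin receptor of dividing cells, rose from 4043 ± 255 to 13430 ± 7541, a change of 1.57 ± 0.33, 2.98-fold (adjusted p = 0.0112). Each of these genes changed in the same direction in 3 of 3 donors.

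Of the other named genes, those that fell were TNFAIP3 (-1.86 ± 0.38) and NFKBIA (-1.55 ± 0.29), both inhibitors of NF-kB signalling, the G protein regulator RGS1 (-1.75), HOXD4 (-1.65) and the monocyte lysozyme LYZ (-1.61 ± 0.44). ZNF267 fell by at least 2.99-fold with 0 of 3 arrays above the floor at 72 h. Those that rose were LTB, lymphotoxin beta (1.90 ± 0.50, 3.72-fold), BST2, the membrane protein tetherin that holds budding HIV-1 (1.68 ± 0.36), and XRCC6 of DNA repair (1.46 ± 0.26). Smaller rises were those of the immunoproteasome subunits PSMB8 (1.24 ± 0.29) and PSMB9 (1.10 ± 0.21), PRDX1 (1.13), cofilin CFL1 (1.07), the splicing protein SNRPB (1.02) and thymidine kinase TK1 (0.99). Each changed in 3 of 3 donors, with adjusted p from 0.00484 to 0.0467, and ZNF267 had 2.63e-04. IL2 (-0.93 ± 0.29, adjusted p = 0.0651) and CDKN1A (-0.59 ± 0.19, adjusted p = 0.0675) did not pass. By limma 78 of 2003 probe sets passed, 13 higher and 65 lower at 72 h, and 440 had an unadjusted p under 0.05. Without the 3 arrays that stood apart 37 were higher and 37 lower. Against 0 h, 51 were higher and 59 lower at 12 h, 42 and 73 at 24 h, and 92 and 168 at 48 h. These tests use the same uninfected 0 h arrays as the infection comparison at 0 h. Without the uninfected array of replicate 2 at 0 h, which had an ACTB 3'/5' ratio of 15.9, 20 passed, TFRC, XRCC6, PSMB9, CXCR4, KLF6, DUSP5, ZNF267 and NFKBIA among them. Without replicate 2 or without replicate 3 the count was 3.

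DNA replication genes rose as a group from 0 h to 72 h, with 16 of 19 members higher (camera adjusted p = 5.53e-04; adjusted p = 0.0251 with an estimated correlation). TK1 rose over all genes tested, and adjusted over the list alone 2 members did, TK1 and the helicase subunit MCM2 (1.29 ± 0.39). MCM7 (0.89 ± 0.32) and the polymerase clamp PCNA (1.10 ± 0.52) were higher in 3 of 3 donors. Proteasome genes were higher in 26 of 28 members (camera adjusted p = 1.09e-05; adjusted p = 0.155 with an estimated correlation), of which 2 rose over all genes tested and 2 adjusted over the list alone. These were PSMB9 and PSMB8, and PSMA2 had 0.90 ± 0.31 and PSMA5 0.66 ± 0.23. RNA splicing genes were higher in 19 of 28 members (camera adjusted p = 0.00608; adjusted p = 0.155 with an estimated correlation). SNRPB rose over all genes tested, and HNRNPA2B1 (1.67 ± 0.48) rose with it adjusted over the list alone. Genes of oxidative phosphorylation were higher in 22 of 28 members (camera adjusted p = 0.0103; adjusted p = 0.155 with an estimated correlation), 0 of which rose over all genes tested or adjusted over the list alone. UQCRC1 had 0.66 ± 0.28 and UQCRC2 -0.53 ± 0.24. NF-kB target genes were lower in 10 of 11 members (camera adjusted p = 0.0161; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 3.45e-04). Over all genes tested 2 fell, NFKBIA and TNFAIP3, joined by BIRC2 (-0.35 ± 0.12) adjusted over the list alone. By fry the DNA replication list had an adjusted p of 0.00116, the proteasome list 0.0857, and the RNA splicing and oxidative phosphorylation lists 0.0985 each. The NF-kB list had a camera adjusted p of 0.109 without replicate 1, and the RNA splicing list 0.103 without replicate 3.

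**Figure D2:**
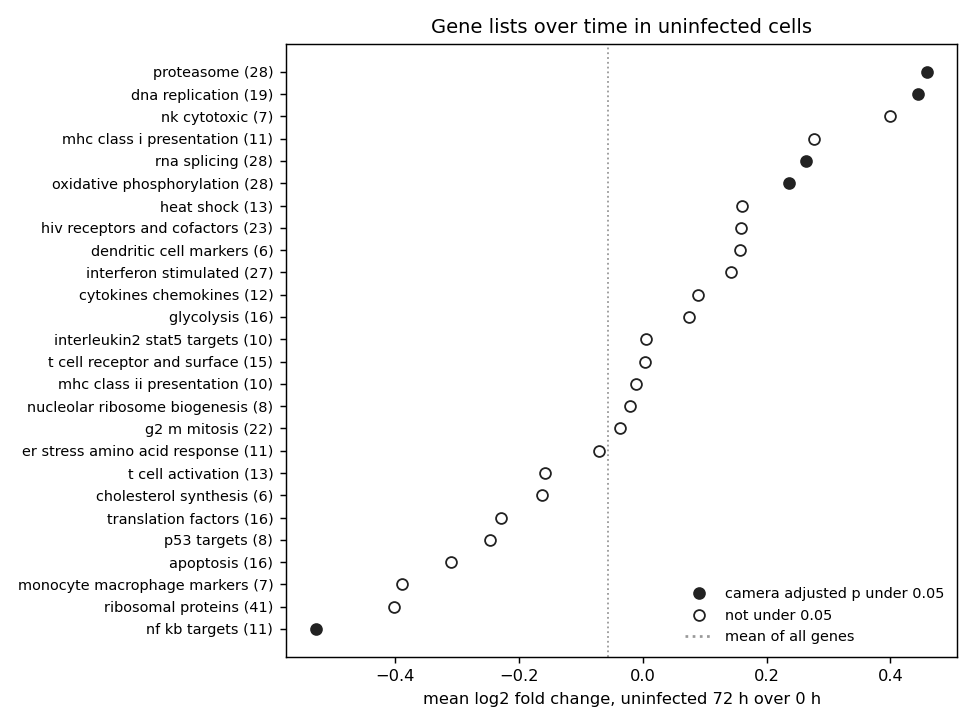
The mean log2 change of the measured members of each of the 26 gene lists tested, uninfected cells at 72 h over 0 h, with filled points where the camera adjusted p was under 0.05 and a dotted line at the mean of all genes. Proteasome genes have the largest mean rise, 0.46, and NF-kB targets the largest mean fall, -0.53.

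Other lists did not pass by camera over this interval in the main fit. Apoptosis genes were lower in 13 of 16 members (camera adjusted p = 0.0885; fry adjusted p = 0.00116). CASP8 (-1.08 ± 0.21, adjusted p = 0.00778) and CFLAR (-0.81 ± 0.17, adjusted p = 0.0127) fell in 3 of 3 donors. Monocyte and macrophage markers were lower in 5 of 7 members (camera adjusted p = 0.291; fry adjusted p = 0.0337). LYZ and the apolipoprotein APOE (-0.50 ± 0.13, adjusted p = 0.0391, lower in 2 donors and higher in 0) fell. The mean intensity of APOE over all arrays was 1458, under the floor. Its change equals its infection difference at 0 h, which uses the same uninfected 0 h arrays, so the 2 are not separate evidence. HIV-1 receptors and cofactors moved both ways, 13 of 23 higher and 9 lower (camera adjusted p = 0.108). XRCC6 and BST2 rose, and CXCR4 and the NF-kB subunit RELA (-0.93 ± 0.26, adjusted p = 0.0498) fell. The interferon-stimulated list had a camera adjusted p of 0.151, T-cell receptor and surface genes 0.686, ribosomal protein genes, lower in 38 of 41 members, 0.216, and genes of mitosis 0.608. Between infected and uninfected cells averaged over 12 to 72 h, monocyte and macrophage markers had a camera adjusted p of 0.864.

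Across all 5 time points of the uninfected cells, 54 of 2003 probe sets changed by the limma F test, with 488 at an unadjusted p under 0.05. KLF6 had the lowest p (adjusted p = 1.19e-05), with log2 changes from 0 h of -1.51 at 12 h, -1.78 at 24 h, -1.52 at 48 h and -1.71 at 72 h. Also lower at each later time were ZNF267 (adjusted p = 5.4e-04), DUSP5 (adjusted p = 7.58e-04) and the adaptor CYTIP (-1.51 at 12 h, adjusted p = 0.00398). The same held for CSNK1D (-0.72 at 12 h, adjusted p = 0.00602), the AP-1 component FOSB (-0.97 at 12 h, adjusted p = 0.00615), TNFAIP3 (-1.80 at 12 h and -2.27 at 48 h, adjusted p = 0.00822) and CASP8 (-1.20 at 12 h, adjusted p = 0.00904). TFRC was higher at each later time, by 1.84 at 12 h and 2.51 at 48 h (adjusted p = 0.0022). PSMB9 was higher by 1.20 at 12 h and 1.48 at 48 h (adjusted p = 0.00398). The count was 0 without replicate 2, 7 without replicate 3 and 341 without replicate 1. It was 171 without the uninfected array of replicate 1 at 48 h and 16 without that of replicate 2 at 0 h.

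**Figure D3:**
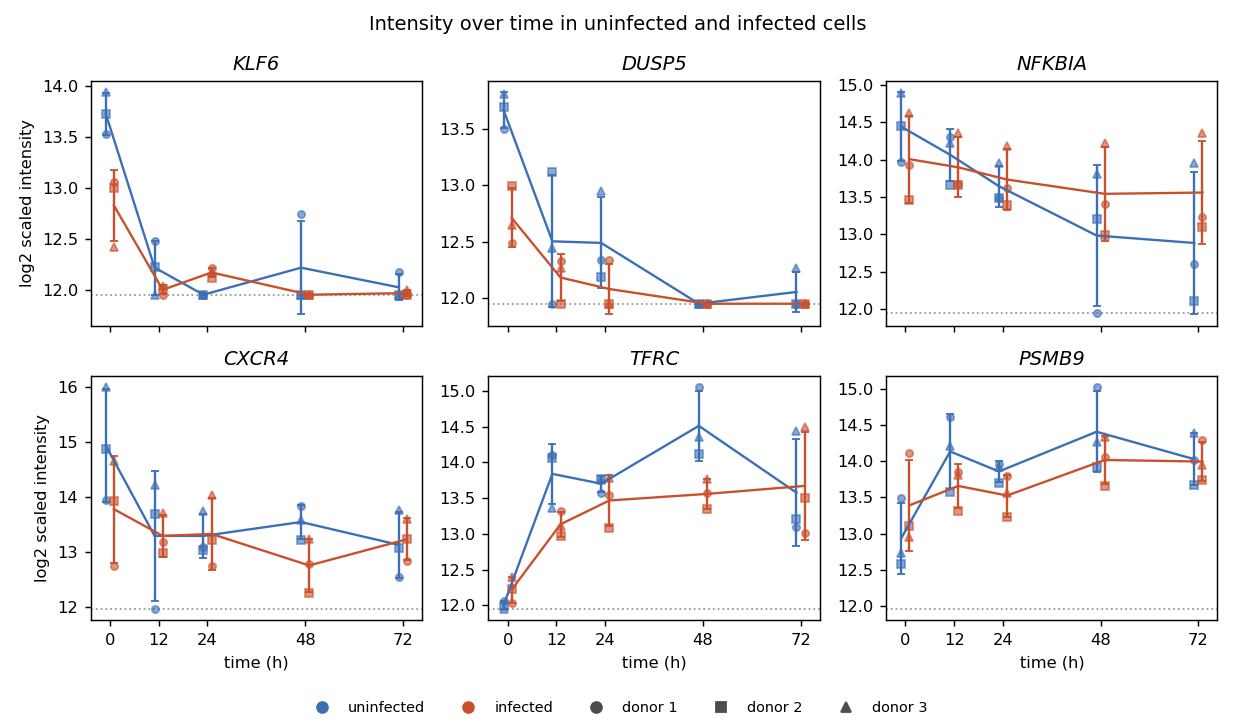
Log2 intensity after the floor against time in hours for KLF6, DUSP5, NFKBIA, CXCR4, TFRC and PSMB9 in infected and uninfected cells, with the mean ± SD of 3 donors as lines, each donor as a point and the floor as a dotted line. In uninfected cells KLF6 is lower by 1.51 at 12 h than at 0 h and TFRC higher by 1.84.

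Array quality differed between groups. The 3'/5' signal ratio of the ACTB control lay between 0.979 and 1.60 on 27 arrays and that of GAPDH between 0.680 and 1.25, whereas 3 uninfected arrays stood apart. They were replicate 1 at 12 h (ACTB 22.3, GAPDH 2.92), replicate 1 at 48 h (GAPDH 0.293) and replicate 2 at 0 h (ACTB 15.9, GAPDH 2.69). Their median correlations with the other arrays of the donor were 0.742, 0.557 and 0.813, against 0.874 to 0.959 on the others. The deposited values had a 2% trimmed mean of about 2005 on 22 arrays and about 2507, 1.25 times as high, on 8 arrays. These 8 were all infected, 5 of replicate 1 and 3 of replicate 2. Every array was therefore scaled to a common trimmed mean. Leaving the values as deposited shifted the mean log2 difference of all probe sets at 48 h from -0.01 to 0.12.

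**Figure D4:**
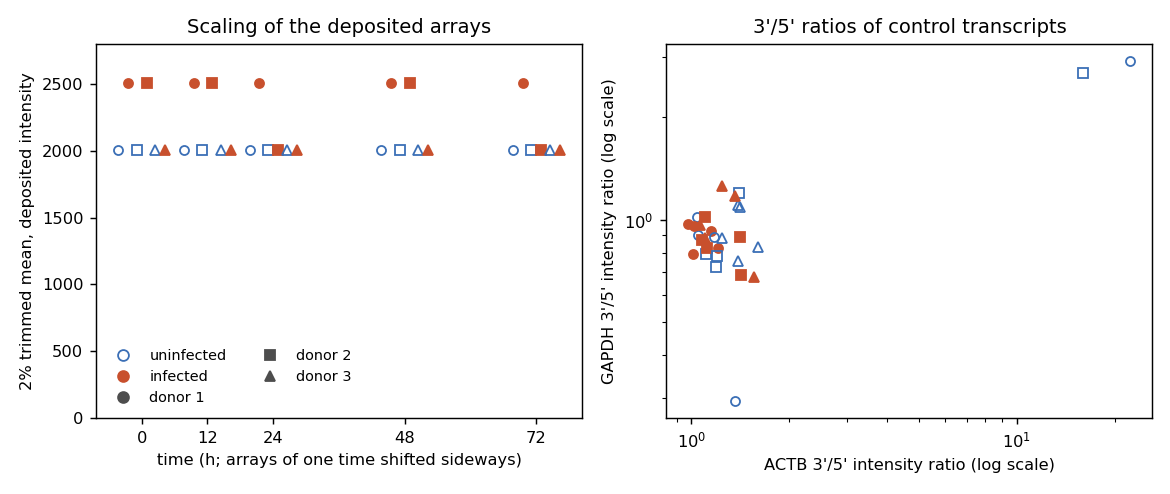
Left, the 2% trimmed mean of the deposited intensity of each of the 30 arrays against time in hours, by infection; right, the ACTB against the GAPDH 3'/5' control ratio of each array, on log axes. Of the arrays, 8 infected ones lie near 2507 and 22 near 2005, and 3 uninfected arrays lie apart in the control ratios.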

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

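Of the tests in this part, those on the degraded RNA of 1 array, on the arrays that stood apart and on the scaling targets were chosen after the result was seen. The others were written down before.

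Interferon-stimulated genes were higher in infected cells at 48 and 72 h by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.768 and 0.176). Of the 3 arrays that stood apart in the control ratios none is a 72 h array, so they are no part of that difference and omitting them is no test of it (adjusted p = 1.44e-07). At 48 h, which holds 1 of them, the adjusted p without them was 0.00023 with the preset correlation. Omission also takes out the pair with the lowest score at 48 h (replicate 1, -0.014), so the lower p does not test that array as a source. The pairs of replicates 2 and 3 at 48 h hold no such array and scored 0.412 and 0.261, so it is no part of the rise in those pairs. The 3 pairs at 48 and 72 h with 1 scaling target had a mean list score of 0.378 (0.261 to 0.534), so differing targets are not the source of the rise in those pairs. The 3 pairs with differing targets (-0.014 to 0.412) include those of replicate 1. Target and donor therefore cannot be told apart across pairs, and every array had already been rescaled. Chance between donors cannot be told apart from an effect of infection, because 3 donors are too few: the exact two-sided sign-flip test over their mean scores, 3 of 3 of them higher, gave p = 0.25, the smallest it allows, and so decides nothing. The list score was also above 0 in 3 of 3 donors at 0 h, and in replicate 1 it was 0.134 at 0 h against 0.058 at 72 h. An interferon response of the infected cultures stays open as a biological explanation and is not weighed here.

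At 0 h more probe sets were lower in infected than in uninfected cells, 236 against 61 at an unadjusted p under 0.05. The mean log2 difference of all probe sets was -0.053 in the main fit and 0.008 under quantile normalization, so this asymmetry depends in part on the scaling. Degraded RNA of the uninfected array of replicate 2 cannot be told apart as a source, since the 504 probe sets lower by over 0.5 in replicate 2 had a median difference relative to all probe sets of 0 in replicate 1 and -0.27 in replicate 3. Part of the count rests on that array: 297 probe sets had an unadjusted p under 0.05 in the main fit and 175 without it. Without replicate 2 there were 61, without replicate 3 147 and without replicate 1 535. Without all 3 arrays that stood apart there were 295. A biological candidate explanation is that infected 0 h cells were at a later point of the decline seen over time in uninfected cells. The correlation across genes between the 0 h infection difference in 1 donor and the uninfected time change in another had a median of 0.094 over 6 pairings, from 0.044 to 0.374. By the limit written beforehand this median counts narrowly against the explanation. The pairings lie on both sides of that limit and genes are not independent replicates, so it is not ruled out.

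Ribosomal protein genes had a higher mean in infected cells at 12 and 48 h by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.949 and 0.652), and at 48 h they were higher in 1 of 3 donors. Without the 3 arrays that stood apart the lower of the adjusted p values was 0.258, and the mean differences were 0.10 at 12 h and -0.05 at 48 h, so those arrays may account for the pattern. No biological explanation was tested.

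Splits of the samples into other groups were counted for each comparison. Where the real count was 0 every split gives at least as many by construction, so the splits test nothing. This holds for infected against uninfected cells over 12 to 72 h (100 of 100 swaps within pairs, highest other 1), for the variation of the difference with time (100 of 100 shuffles, highest other 1), and at 12, 24, 48 and 72 h (10 of 10 splits, highest other 0). At 0 h 4 of the 10 splits gave 3 or more (real 3, highest other 92). The split with 92 set both arrays of replicate 1 and the infected array of replicate 2 against the rest. Those arrays had 1147 (uninfected), 1103 and 1243 probe sets above the floor. The rest had 1494 and 1408 (uninfected replicates 2 and 3) and 1289 (infected replicate 3). Whether this difference accounts for the 92 was not tested. Among the 4 splits that part all 3 pairs the real one was the only one as large at 0 h (highest other 1). For uninfected cells at 72 h against 0 h, 1 of 10 splits gave 78 or more (real 78, highest other 2, and 0 among the 4 that part all pairs). Splits of 6 arrays are too few for a share under 0.05. For time in uninfected cells 9 of 100 shuffles within donors gave 54 or more (highest other 230), so chance is not excluded, and the shuffle with 230 points to a structure of the samples that was not tested.

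For 9 named genes the infection difference was positive in 3 of 3 donors at 1 time and negative in 3 of 3 at another. The tests of whether their differences varied with time gave an adjusted p of 0.998 for each. From 0 h to a later time the log2 difference changed by 1.307 for CDA (72 h), 1.106 for NFKBIA (72 h), 1.121 for KLF6 (24 h) and 1.272 for SRF (48 h), each lower at 0 h and higher later. It was 1.048 higher at 0 h than at 12 h for CSNK2B, 0.932 higher at 0 h than at 12 h for PSMB9, and 0.721 higher at 0 h than at 24 h for FAH. It was 0.912 higher at 24 h than at 12 h for ATXN2L and 0.975 for FKBP2.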

How the results depend on the processing

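The omission of arrays that stood apart, array weights, 0.1 times the floor and list tests on values as deposited were chosen after the data were seen. Of the named genes' values under the alternatives, 2256 kept their side of the threshold, those without a call moving by at most 1 SE. Another 241 without a call moved by more than 1 SE of the main fit. A further 56 passed where they had not, and 151 no longer passed. Of those that passed in the main or the alternative fit, 0 changed direction. Directions were not compared where neither fit passed. Of the 18 list calls, 1 held with an estimated correlation, 3 with fry, 12 with quantile normalization, 13 on values as deposited, 16 with the mean over a gene's probe sets, 13 without the 3 arrays that stood apart, and 13, 9 and 9 without replicate 1, 2 and 3. The cause of the changes below was not tested unless stated. Signal over background limits the results, since 182 of 2003 probe sets were above the floor on every array. Counts not given stayed within 1.5 times the main count.

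For infection over 12 to 72 h (0), the count was 3 on values as deposited, 1 without the 3 arrays, 48 with array weights, and 0 to 11 leaving out replicates or single arrays (11 without replicate 1, 1 without the uninfected 12 h array of replicate 1). At 0 h (3) it was 7 with 0.5 times the floor, 20 with 0.1 times the floor, 1 with quantile normalization, 0 with the filter of 15 arrays, 66 with trend and robust moderation, 11 without the 3 arrays, 73 with array weights and 0 to 233 leaving out replicates or single arrays (5 and 6 without the uninfected 12 h and 48 h arrays of replicate 1). At 12 h (0) it was 2 without the 3 arrays, 2 with array weights and 0 to 4 leaving out replicates. At 24 h (0) it was 0 to 2 leaving out replicates. At 48 h (0) it was 1 without the 3 arrays, 1 with array weights, 1 without the uninfected 48 h array of replicate 1, and 0 to 2 leaving out replicates. At 72 h (0) it was 1 with array weights and 0 to 2 leaving out replicates. For infection by time (0) it was 1 with 0.5 times the floor, 2 with 2 times the floor, 1 without the 3 arrays and 0 to 24 leaving out replicates or single arrays (1 without the uninfected 0 h array of replicate 2).

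For time in uninfected cells (54) the count was 91 with 0.5 times the floor, 98 with trend and robust moderation, 82 without the 3 arrays, 229 with array weights and 0 to 341 leaving out replicates or single arrays (171 without the uninfected 48 h array of replicate 1, 16 without the 0 h array of replicate 2). For uninfected cells at 72 h against 0 h (78) it was 41 with 2 times the floor, 50 on values as deposited, 22 with the filter of 15 arrays, 131 with trend and robust moderation, 243 with array weights and 3 to 422 leaving out replicates or single arrays (20 without the 0 h array of replicate 2, 133 and 221 without the 12 h and 48 h arrays of replicate 1). Quantile normalization gave 53, with 17 higher and 36 lower, and omission of the 3 arrays 74, with 37 and 37.

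Without the replicate block the counts were 23 for time in uninfected cells and 18 for 72 h against 0 h, and no other count moved by over 1.5 times. With the replicate block and only the 6 arrays of a comparison, the counts were 0 at 0 h and 0 for uninfected 72 h against 0 h, where fewer samples estimate the spread. With the replicate block within each time the count at 0 h was 3, but KLF6 and RGS16 did not pass (adjusted p = 0.117 and 0.112).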

Other observations

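The array weights behind the first paragraph of this part were chosen after the data were seen. The weights were estimated by limma from how closely each array followed the same linear model, and are no separate measure of quality. The uninfected 0 h array of replicate 1 had a weight of 0.206 with control ratios of 1.05 (ACTB) and 0.898 (GAPDH). With these weights, 48 probe sets differed between infected and uninfected cells over 12 to 72 h. Among them were 38 genes with 1 symbol, 24 higher and 14 lower, of which 24 had the same direction in 3 of 3 donors. SLA was higher (log2 difference 0.41 ± 0.06 SE, adjusted p = 0.00232, 3 of 3 donors), and it also passed without the 3 arrays that stood apart (0.43, adjusted p = 0.0205). Cyclin D3 (CCND3, 0.37 ± 0.07), the sialomucin CD164 (0.52 ± 0.10), CCL5 (0.47 ± 0.11) and cytidine deaminase CDA (0.47 ± 0.12) were higher in 3 of 3 donors, with adjusted p from 0.0104 to 0.0391. Of 27 interferon-stimulated genes 5 passed, all higher in infected cells: ISG15, PLSCR1, IFI44, ADAR and GBP1. CKS2 (-0.45 ± 0.11), SLC25A5 (-0.34 ± 0.09) and lysozyme LYZ (-0.53 ± 0.13) were lower in 3 of 3 donors, with adjusted p from 0.0369 to 0.0381. Without weights 0 probe sets passed, and without the 3 arrays 1 did.

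Of the lists of other cell types, 4 had fewer than 5 measured members and were not tested as groups. The B-cell markers CR2 and CD79A had log2 changes of -1.18 ± 0.34 (SE, adjusted p = 0.0508) and -0.33 ± 0.13 (adjusted p = 0.15) in uninfected cells from 0 h to 72 h, and CD37 0.38 ± 0.44 (adjusted p = 0.679). CR2 and CD79A had mean intensities over all arrays of 3473 and 1165, under the floor. Their changes equal their infection differences at 0 h, which use the same uninfected 0 h arrays. The plasma cell marker XBP1 had -0.05 ± 0.32 (adjusted p = 1) and the platelet marker SELP -1.07 ± 0.45 (adjusted p = 0.167). Granulocyte markers had 0 measured members. Natural killer and cytotoxic genes were higher in 6 of 7 members over this interval (camera adjusted p = 0.151), with granulysin (GNLY) at 1.01 ± 0.56 in 3 of 3 donors (adjusted p = 0.293), and dendritic cell markers had a camera adjusted p of 0.4. Between infected and uninfected cells over 12 to 72 h, CR2 had -0.12 ± 0.17, CD37 -0.01 ± 0.22, XBP1 0.17 ± 0.16 and SELP -0.14 ± 0.23, none of which passed by limma.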
